A study of Mus musculus with 32 samples.

How the data were processed

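RNA sequencing values of 32 libraries were analysed: 4 vehicle and 4 auranofin libraries each from iWAT, eWAT, liver and BAT of mice on a 60% fat diet, made from total RNA with a kit that keeps no strand. Groups were taken from the sample labels, and no library was left out. Same-numbered libraries were not treated as pairs. The labels do not say how many animals were used.

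The deposited table gives FPKM for 54532 genes, which the authors computed by dividing reads per gene by gene length and by 1 library size per library. The submitters' processing notes name CASAVA, STAR 2.6.1d, featureCounts 1.5.0-p3 and DESeq2 1.20.0 on mm10, without saying what each was used for or in what order. Multiplying each value by gene length gave whole multiples of 1 step per library, within 0.1 read in 100% of values, so whole reads were rebuilt. The rebuilt reads numbered 13606756 to 19205640 per library and fell on 18970 to 22594 genes. The library size in the table was not this sum but a rescaled one, between 10559760 and 24013795. Its ratio to size factors computed here as medians of ratios was 1 in each library. Of the gene identifiers, 54409 were found in GENCODE release 21 of the mouse annotation, 100% on the same chromosome and 98.33% with the same start and end. Symbols shared by several identifiers numbered 102, and 27 symbols had the form of a date, so genes were followed by identifier. Reads of overlapping genes on opposite strands, and of near-identical copies such as globin, immunoglobulin and major urinary protein genes, cannot be parted, and values of such genes are uncertain.

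Each tissue was fitted alone with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with an intensity trend in the empirical Bayes step. Genes with a mean FPKM of 0.5 or more over the 8 libraries were tested, and a Benjamini-Hochberg adjusted p under 0.05 was the threshold. Whether a change differed between tissues was tested as an interaction over the libraries of eWAT and iWAT, of eWAT and BAT, of iWAT and BAT, and of liver against the mean of the fat depots. The 36 gene lists, 1170 entries in all with 2 absent from the table, were tested with camera at its preset correlation of 0.01 where 5 or more members passed the filter. The list of epididymis and testis genes had too few members in every tissue (0 in iWAT, 1 in eWAT, 3 in liver and 0 in BAT of 32), and in BAT the T and NK cell, mesothelial and epithelial lists did too. Each list was also tested with a correlation estimated from the data and with fry, and its members were adjusted over the list alone. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

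The comparisons, tests, lists and rule for naming genes were set before the data were examined. The rule names 8 genes in every tissue: Lep, Adipoq, Ucp1, Adgre1, Txnrd1, Nqo1, Mt1 and Mt2. It adds up to 7 protein-coding genes per direction with the largest change among those that passed, had a mean FPKM of 1 or more in a group and did not overlap between groups. Where fewer than 5 passed in a direction, those with the smallest p that met the same conditions filled up to 5 and are given as not passing. It also adds the 4 members with the smallest p of each called list, and 5 genes per direction for each interaction. Many genes that the rule allows are not reported here. Copies of named genes, and genes called under single settings, are named outside the rule, after their values were seen.

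The fits were tested on simulated data with known changes in 67 genes at 1.5-fold, 67 at 2-fold and 66 at 4-fold. The share recovered at these folds was 13.4%, 59.7% and 92.4% in iWAT, 1.49%, 43.3% and 87.9% in eWAT, 29.9%, 70.1% and 97.0% in liver, and 23.9%, 73.1% and 92.4% in BAT. For the interactions it was 1.49%, 29.9% and 80.3% between eWAT and iWAT, 5.97%, 29.9% and 87.9% between eWAT and BAT, 4.48%, 46.3% and 90.9% between iWAT and BAT, and 13.4%, 79.1% and 95.5% between liver and fat. The simulated list was called in each tissue, which vouches for no list call: regrouped real libraries gave them too. False calls were 6 in iWAT, 3 in eWAT, 11 in liver and 12 in BAT. The interactions had 13, 7, 9 and 16 in the same order. Only eWAT kept them under 0.05 of calls. With n = 4 most 1.5-fold changes would be missed.

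Alternatives tried were pseudocounts, filters, scalings (TPM scale, median ratios and quantile normalisation), sample quality weights, no intensity trend, voom on the rebuilt reads, protein-coding genes alone, a replicate block (with statmod 1.5.0), 1 fit of all libraries, a looser threshold, and leaving out each library. Removal of a gene-length trend (lowess span 0.3), a skeletal muscle covariate, leaving out pairs of libraries, the TPM scale for lists and leaving libraries out of the correlations between tissues were added after the data were seen.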

Results

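RNA sequencing was done on 4 tissues of C57Bl/6 mice: inguinal white fat (iWAT, a subcutaneous depot), epididymal white fat (eWAT, a visceral depot), liver and brown fat (BAT). The mice ate a 60% fat diet for 12 weeks. They then received vehicle or auranofin, a gold-containing anti-rheumatic drug that inhibits thioredoxin reductase, at 1 mg per kg of body weight 3 times a week for 4 weeks. Each tissue had 4 vehicle and 4 auranofin libraries, 32 in all. The reads assigned to genes numbered 16015264 to 18436456 per library in iWAT, 15031255 to 17068533 in eWAT, 14981602 to 18109130 in liver and 13606756 to 19205640 in BAT. All values are means ± SD of FPKM over 4 libraries unless another number is given. Each log2 change is auranofin minus vehicle on the log2(FPKM + 1) scale, which understates the change of genes at low levels. P-values measure the spread between libraries only, since nothing in the labels says that the libraries came from separate animals. P-values of genes come from limma and those of lists from camera. Genome positions are on the mouse build mm10.

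The libraries carried the marker genes of the tissues they were named for. Alb, which encodes the liver protein albumin, stood at 47427 ± 6871 FPKM over the 8 liver libraries. Adipoq, the adipocyte hormone adiponectin, stood at 2599.8 ± 573 FPKM in iWAT, 1634 ± 738 in eWAT and 619 ± 82.5 in BAT. Ucp1, the uncoupling protein of brown adipocytes, stood at 2817 ± 711 FPKM in BAT, 0.152 ± 0.108 in iWAT and 0.239 ± 0.152 in eWAT, and no read was assigned to it in liver. Ucp1 was too low to be tested in iWAT, eWAT and liver, as were Lep, Adipoq and Mt2 in liver.

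The series title names leptin, so Lep (ENSMUSG00000059201, chromosome 6, 29060220 to 29073877), the gene of the adipocyte hormone that signals fat stores to the brain, was compared in every tissue. In iWAT, Lep had 1369 ± 564 FPKM with auranofin against 1651 ± 81.9 with vehicle (log2 change -0.35, SE 0.26, limma adjusted p = 0.421, n = 4 each). It was lower than the vehicle mean in 3 of 4 auranofin libraries, while auranofin library 2 had 2211 FPKM, the highest of the 8. In eWAT, Lep had 664 ± 354 against 714 ± 207 FPKM (log2 change -0.21, SE 0.42, adjusted p = 0.801), lower in 3 of 4 auranofin libraries. In BAT, it had 55.6 ± 38.9 against 98.7 ± 41.5 FPKM (log2 change -0.94, SE 0.42, adjusted p = 0.448), lower than the vehicle mean in 3 of 4. In liver at most 1 read per library fell on Lep. None of these tests passed the threshold of 0.05. Without auranofin library 2 the Lep change in iWAT was -0.60, 1 of 4819 that passed (adjusted p = 0.00314). With sample quality weights it was -0.53, 1 of 6095 that passed (0.00796), and quantile normalisation gave 0.032. Over the settings tried, its adjusted p was 0.00314 to 0.907. Without eWAT auranofin library 2 the eWAT change turned to 0.12.

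**Figure D1:**
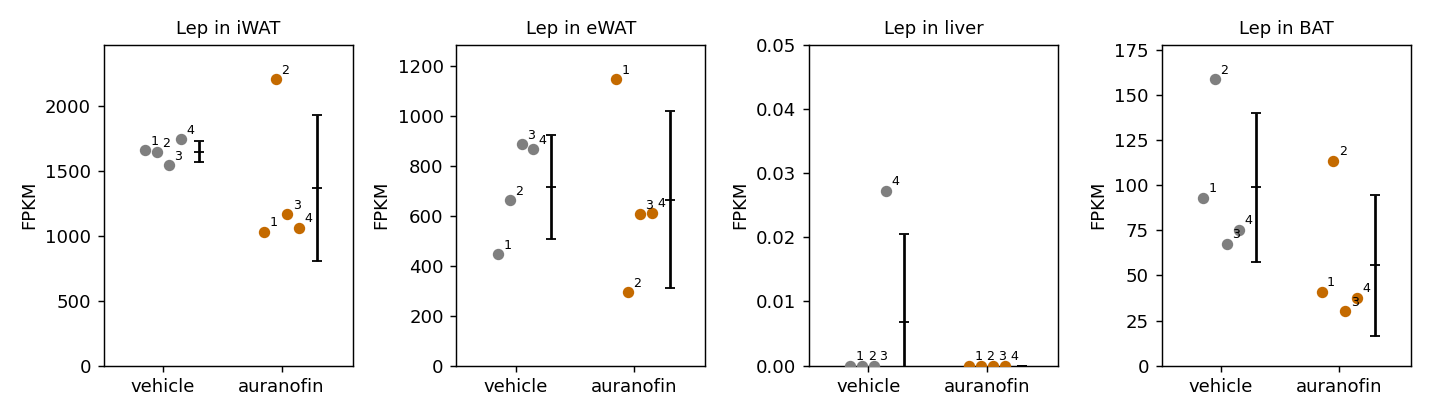
Lep in each of the 32 libraries as FPKM (y axis, separate scale per tissue), with the mean and SD of the 4 vehicle and 4 auranofin libraries of each tissue. In iWAT the auranofin libraries lie between 1034 and 2211 FPKM, and the mean change of -0.35 turns to 0.032 after quantile normalisation.

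In iWAT the comparison asked which transcripts differed after auranofin in a subcutaneous white depot, and transcripts of mitochondrial energy metabolism were lower as groups. All 70 nuclear-encoded genes of oxidative phosphorylation had log2 changes below 0 (median -0.72, camera adjusted p = 5.65e-16, or 0.696 with an estimated correlation). The median was -0.52 with the gene-length trend removed and -0.46 in lists matched on length and abundance, both chosen after the data were seen. Ndufs4, a subunit of respiratory complex I, had 27.4 ± 14.0 FPKM with auranofin against 52.4 ± 5.09 with vehicle (log2 change -1.02, SE 0.27), and Atp5h, a subunit of ATP synthase, had 118 ± 42.7 against 200.4 ± 36.7 FPKM. All 13 transcripts encoded by mitochondrial DNA were also below 0 (median -0.69, adjusted p = 1.02e-06; adjusted p = 0.696 with an estimated correlation). Among them mt-Co2, a core subunit of cytochrome oxidase, had 79.0 ± 66.2 against 201 ± 42.4 FPKM (log2 change -1.60, SE 0.43) and mt-Atp6, of ATP synthase, had 74.0 ± 65.2 against 247 ± 139.7 FPKM. Reads on ribosomal and small nucleolar RNA genes moved with these lists. Those on ribosomal RNA genes made up 0.229% to 0.247% of reads in genes in auranofin libraries 1, 3 and 4, against 0.0684% to 0.121% with vehicle and 0.0847% in auranofin library 2, and those on small nucleolar RNA genes 0.00257% to 0.00322%, against 0.00115% to 0.00174% and 0.00112%.

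Fatty acid oxidation genes and targets of PPAR-alpha, the receptor that controls them, fell in iWAT (28 of 33 below 0, median -0.36, adjusted p = 0.000375). Acadl, which starts the oxidation of long-chain fatty acids, had 198 ± 68.7 against 295 ± 15.8 FPKM (log2 change -0.62, SE 0.21). The adipokine list, of hormones and other proteins secreted by fat, fell (19 of 20 below 0, median -0.42, adjusted p = 0.000375). Its members Retn, which encodes resistin, had 592 ± 242 against 1073 ± 178 FPKM (log2 change -0.92, SE 0.27), Sncg had 1564 ± 630.3 against 2550.0 ± 522 FPKM and Igf1, a growth factor, had 16.8 ± 2.64 against 23.4 ± 3.29 FPKM. The list of the thioredoxin system and selenoproteins, to which the drug's known target belongs, fell (30 of 34 below 0, median -0.41, adjusted p = 0.000126). Sephs2, which makes the selenium donor for selenoproteins, had 14.4 ± 3.78 against 24.8 ± 4.37 FPKM (log2 change -0.76, SE 0.18), Selenof had 64.3 ± 10.9 against 92.5 ± 11.4 FPKM and Prdx1, a peroxidase fed by thioredoxin, had 122 ± 27.9 against 178 ± 26.0 FPKM. Txnrd1 itself, the cytosolic thioredoxin reductase, had 9.66 ± 0.750 against 9.27 ± 0.420 FPKM (log2 change 0.052, SE 0.088, adjusted p = 0.726). For each of these 3 lists the adjusted p = 0.696 with an estimated correlation.

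Smaller shifts were found in 5 other functional lists in iWAT. Mature white adipocyte genes had a median of -0.33 (18 of 24 below 0, adjusted p = 0.0488), which turned to 0.17 and a call in the other direction after quantile normalisation. Agpat2, of triglyceride synthesis, had 251 ± 166 against 416 ± 79.7 FPKM. Adrb3, the beta-3 adrenergic receptor, had 27.5 ± 12.9 against 14.6 ± 4.18 FPKM (log2 change 0.80, SE 0.35). Cholesterol synthesis genes fell (19 of 23 below 0, median -0.25, adjusted p = 0.0122), with Hmgcs1, an early enzyme of that pathway, at 84.0 ± 21.8 against 131 ± 20.6 FPKM. With an estimated correlation the adjusted p = 0.720 for the adipocyte list and 0.844 for the cholesterol list. Targets of NRF2, the regulator of antioxidant genes, had a median of -0.24 (27 of 40 below 0, adjusted p = 0.0343), but -0.0040 after quantile normalisation. Akr1b8 had 21.2 ± 2.22 against 28.7 ± 2.99 FPKM and Ephx1, which detoxifies epoxides, had 46.7 ± 6.65 against 32.1 ± 4.92 FPKM. The list of the unfolded protein and integrated stress response had a median of -0.17 (31 of 40 below 0, adjusted p = 0.0126), but 0.040 after quantile normalisation. Its members Manf, an endoplasmic reticulum protein, had 10.1 ± 1.23 against 14.2 ± 1.49 FPKM and Fgf21, a hormone made under nutrient stress, had 0.918 ± 0.226 against 2.06 ± 0.982 FPKM. Immediate-early genes, which respond within minutes to stimuli, rose (19 of 28 above 0, median 0.18, adjusted p = 0.0375), with Fosb at 2.82 ± 2.15 against 0.445 ± 0.0541 FPKM and Btg2 at 23.6 ± 4.56 against 16.3 ± 2.48 FPKM. For the NRF2, stress response and immediate-early lists the adjusted p = 0.696 with an estimated correlation.

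Markers of other cell types also differed between the iWAT groups. Hepatocyte markers fell (29 of 30 below 0, median -1.04, adjusted p = 0.000126). Vehicle library 1 had 217 FPKM of Alb against 9.74 to 25.0 in the other libraries, and without it the median was -0.53. Within the list Trf, which encodes transferrin, had 44.7 ± 14.99 against 84.7 ± 26.9 FPKM and Cyp2e1, which is also expressed in fat, had 114 ± 43.9 against 240.1 ± 111 FPKM. B cell and lymph node markers fell (16 of 16 below 0, median -0.78, adjusted p = 0.00615), with Ighm, the IgM heavy chain, at 441 ± 185 against 711 ± 60.8 FPKM (log2 change -0.76, SE 0.26). Red blood cell markers fell (9 of 9 below 0, median -0.51, adjusted p = 0.0205), with Hbb-bs, a beta globin with near-identical copies, at 282 ± 105 against 506 ± 126 FPKM. Endothelial markers rose (22 of 26 above 0, median 0.38, adjusted p = 0.00195), with Flt1, a VEGF receptor, at 6.80 ± 2.12 against 3.95 ± 0.800 FPKM and Stab1 at 8.11 ± 1.75 against 5.13 ± 2.02 FPKM. For each of these 4 lists the adjusted p = 0.696 with an estimated correlation. Skeletal muscle markers had a median of -0.041 and were not called (adjusted p = 0.739), while their mean log2 level was 4.48 in vehicle library 4 and 3.75 in auranofin library 4 against 0.895 to 1.18 elsewhere.

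In all, 14 of 35 lists tested in iWAT were called, 2 higher and 12 lower, and quantile normalisation gave 12, 4 higher and 8 lower. No measured list member was called over all genes, and adjusted over the list alone 6 of the mitochondrially encoded transcripts were lower and no member of the other 13 called lists passed. No gene passed over all 13164 genes tested by limma, where the smallest adjusted p was 0.204. At an unadjusted p under 0.05 there were 1207 higher and 1688 lower genes, and voom on rebuilt reads also called 0. The groups did not overlap in 682 genes, 5.18% of those tested, against 2.86% by chance. Nearest to the threshold among those lower in 4 of 4 auranofin libraries were Pcolce2, which enhances collagen processing (16.6 ± 2.57 against 32.7 ± 5.02 FPKM), Gtf2f2, a subunit of a general transcription factor (9.26 ± 0.914 against 15.7 ± 2.28 FPKM), Bcar3 (32.8 ± 3.69 against 53.1 ± 4.40 FPKM) and Smtnl2 (2.48 ± 0.830 against 7.24 ± 1.94 FPKM). Among those higher in 4 of 4 were Thbs1, the matrix protein thrombospondin (21.1 ± 3.95 against 12.0 ± 1.07 FPKM), Ubn1, a histone chaperone subunit (5.45 ± 0.864 against 3.10 ± 0.417 FPKM), and Dapk1, a kinase of cell death (8.96 ± 0.308 against 6.40 ± 0.656 FPKM). Adipoq had 2270.3 ± 679 against 2929 ± 121 FPKM (log2 change -0.41, SE 0.24), which turned to 0.15 after quantile normalisation. Adgre1, the macrophage marker F4/80, had 9.56 ± 2.72 against 7.42 ± 3.73 FPKM, and Nqo1, a classical NRF2 target, had 4.62 ± 1.29 against 4.39 ± 0.489 FPKM. The metallothioneins Mt1 and Mt2, which bind metals, had 97.4 ± 50.7 against 90.9 ± 20.9 FPKM and 1.06 ± 1.04 against 1.14 ± 0.662 FPKM, with log2 changes of -0.041 and -0.14; that of Mt1 was 0.29 after quantile normalisation.

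The iWAT counts rested on auranofin library 2. Its mean log2 level over the oxidative phosphorylation list was 6.89, against 5.55 to 5.89 in the other auranofin libraries and 6.56 to 6.80 in the vehicle libraries. It had reads on 19949 genes, against 21667 to 21924 in the other auranofin libraries and 19839 to 21368 with vehicle. Short genes were lower and long genes higher in iWAT after auranofin: the median log2 change ran from -0.653 for protein-coding genes up to 500 nt to 0.0863 for those over 6000 nt. Without that library limma called 4819 genes, 2000 higher and 2819 lower; sample quality weights gave 6095 (2631 higher, 3464 lower) and 1 fit of all 32 libraries 722 (270 higher, 452 lower). Of the 14 lists, 8 were called whichever library was left out. The mature adipocyte list lost its call without vehicle library 1 (adjusted p = 0.0689), vehicle 3 (0.0781), auranofin 1 (0.0692), auranofin 3 (0.114) or auranofin 4 (0.105), and the immediate-early list without vehicle 1 (0.122), vehicle 3 (0.0881), auranofin 1 (0.178) or auranofin 2 (0.195). The cholesterol list lost its call without vehicle 2 (0.0793) or auranofin 4 (0.0538), the NRF2 list without vehicle 1 (0.0510) or auranofin 3 (0.0911), the B cell list without vehicle 1 (0.103) or auranofin 2 (0.136), and the red blood cell list without vehicle 4 (0.0518), auranofin 1 (0.102) or auranofin 2 (0.129). Without auranofin library 2 the medians were -0.43 for cholesterol synthesis, -0.26 for the stress response and 0.57 for endothelial markers, and the last was 0.24 without auranofin library 3. Quantile normalisation ended the calls of the adipokine, fatty acid oxidation, NRF2, stress response and red blood cell lists, and the TPM scale those of the mature adipocyte, NRF2, stress response and immediate-early lists. Removal of the gene-length trend, chosen after the data were seen, ended the calls of the mature adipocyte (0.0737), NRF2 (0.162), stress response (0.0737) and red blood cell lists (0.106), and a pseudocount of 0.1 that of the mature adipocyte list (0.0548). TPM scaling moved the median change of all genes from -0.0166 to 0.234 in iWAT, from 0.00288 to -0.142 in eWAT and from 0.0218 to -0.0973 in BAT, so its directions are read relative to these shifts.

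**Figure D2:**
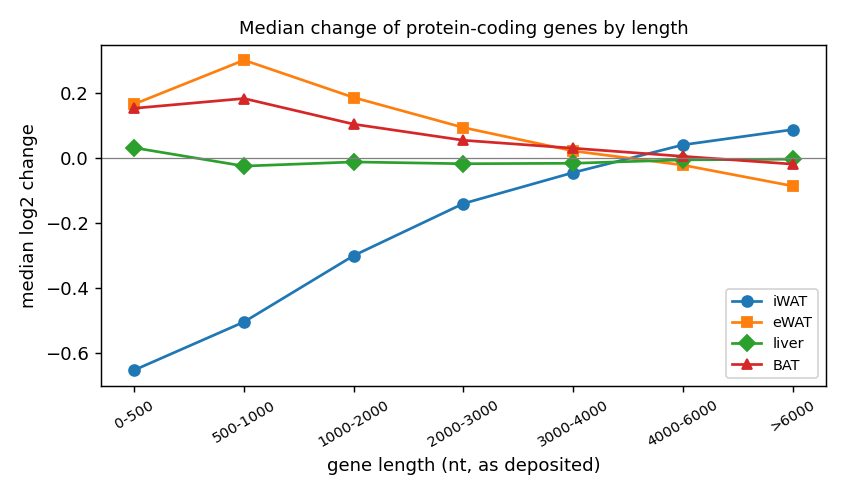
Median log2 change (y axis) of protein-coding genes grouped by gene length in nt (x axis), 1 line per tissue. In iWAT the median runs from -0.653 (up to 500 nt) to 0.0863 (over 6000 nt).

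In eWAT, the comparison asked the same of a visceral white depot, and adipocyte genes were higher and matrix, cell division and macrophage genes lower as groups. Vehicle libraries 1 and 2 stood apart, at 34.97 and 56.77 on the first principal component (54.28% of the variance), while vehicle libraries 3 and 4 (-7.26 and -6.658) lay near the auranofin libraries (-33.05 to -9.124). Without those 2 libraries, an alternative chosen after the data were seen, 15 lists were called and the adipocyte, lipolysis and macrophage lists were not. Mature white adipocyte genes rose (20 of 24 above 0, median 0.57, adjusted p = 0.000229). Adrb3 (chromosome 8, 27225776 to 27250616) had 85.0 ± 31.1 FPKM with auranofin against 23.8 ± 18.5 with vehicle (log2 change 2.09, SE 0.54), Pck1, which makes glycerol phosphate for fat storage, had 367 ± 189 against 107 ± 77.7 FPKM (log2 change 1.93, SE 0.53) and Slc2a4, the insulin-responsive glucose transporter, had 43.3 ± 15.5 against 17.2 ± 11.6 FPKM (log2 change 1.48, SE 0.48). Lipolysis and beta-adrenergic genes rose (19 of 27 above 0, median 0.35, adjusted p = 0.0355), with the lipases Lipe at 207 ± 52.3 against 114 ± 55.0 FPKM and Pnpla2 at 502 ± 167 against 269 ± 119 FPKM. Both had an adjusted p = 0.660 with an estimated correlation, as did every other list called in eWAT. Without vehicle libraries 1 and 2 their medians were 0.095 (adjusted p = 0.142) and -0.012 (0.807).

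Nuclear-encoded genes of oxidative phosphorylation, fatty acid oxidation genes and the thioredoxin list rose in eWAT, while mitochondrially encoded transcripts (10 of 13 below 0, median -0.041, adjusted p = 0.398) and NRF2 targets (adjusted p = 0.218) were not called. Of the nuclear-encoded genes of oxidative phosphorylation, 65 of 70 were above 0 (median 0.41, adjusted p = 3.71e-09; adjusted p = 0.660 with an estimated correlation), with Ndufs7 of complex I at 57.4 ± 14.7 against 33.2 ± 13.4 FPKM. Short genes were higher in eWAT, the reverse of iWAT. The median log2 change was 0.30 for protein-coding genes of 500 to 1000 nt and -0.087 for those over 6000 nt (Spearman correlation of change with length -0.237). With that trend removed, chosen after the data were seen, the oxidative phosphorylation median was 0.30 and still called. Fatty acid oxidation genes and PPAR-alpha targets had a median of 0.28 (26 of 33 above 0, adjusted p = 0.00722). Members that ran against the direction of the list were among the 4 with the smallest p: Cpt1a, which carries fatty acids into mitochondria, had 26.7 ± 2.17 against 37.9 ± 5.84 FPKM and Plin2, a lipid droplet protein, had 187 ± 60.9 against 306 ± 95.3 FPKM. The thioredoxin and selenoprotein list had a median of 0.15 (23 of 34 above 0, adjusted p = 0.0261), with Gpx4, which reduces lipid peroxides, at 456 ± 194 against 226 ± 84.4 FPKM, Selenow at 669 ± 221 against 383 ± 120.1 FPKM and Sod1 at 89.0 ± 22.1 against 57.1 ± 12.2 FPKM. Txnrd1 had 10.4 ± 0.714 against 12.7 ± 2.33 FPKM (log2 change -0.25, SE 0.15, adjusted p = 0.447). Without vehicle libraries 1 and 2 the oxidative phosphorylation median was 0.18 and still called, and that of fatty acid oxidation 0.033 and not called (adjusted p = 0.436). For the fatty acid oxidation and thioredoxin lists, too, the adjusted p = 0.660 with an estimated correlation.

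Extracellular matrix genes fell in eWAT (37 of 46 below 0, median -0.60, adjusted p = 4.72e-08; adjusted p = 0.660 with an estimated correlation). Col6a3, a chain of collagen VI, had 12.0 ± 3.09 against 23.1 ± 1.90 FPKM (log2 change -0.92, SE 0.20), Fbn1, fibrillin, had 8.96 ± 2.45 against 19.8 ± 5.89 FPKM, Mmp14, a matrix protease, had 10.9 ± 1.29 against 18.3 ± 3.36 FPKM and Col3a1 had 64.4 ± 21.5 against 165 ± 83.6 FPKM. Cell cycle genes fell (38 of 39 below 0, median -0.55, adjusted p = 4.86e-15), with Ccnb1, the mitotic cyclin, at 0.642 ± 0.219 against 1.78 ± 0.678 FPKM, Aurka, a mitotic kinase, at 1.13 ± 0.437 against 2.28 ± 0.557 FPKM and Top2a at 1.07 ± 0.464 against 3.13 ± 1.56 FPKM. Fibroblast and adipocyte progenitor markers fell (18 of 26 below 0, median -0.20, adjusted p = 0.0258), with Lum, a matrix proteoglycan, at 39.0 ± 11.1 against 124 ± 72.5 FPKM (log2 change -1.48, SE 0.43) and Vcan at 0.858 ± 0.187 against 2.58 ± 1.59 FPKM. Both lists had an adjusted p = 0.660 with an estimated correlation. Without vehicle libraries 1 and 2, matrix genes stood at -0.35 and cell cycle genes at -0.35, both called, and the fibroblast list was not called (median -0.16, adjusted p = 0.0649).

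Immune cell markers moved in both directions in eWAT. Macrophage markers fell (25 of 30 below 0, median -0.50, adjusted p = 0.000190), with Adgre1 at 41.5 ± 17.9 against 73.9 ± 25.4 FPKM (log2 change -0.85, SE 0.35) and Itgax, or CD11c, at 19.1 ± 11.1 against 47.0 ± 21.0 FPKM. The mean log2 level of the list was 5.12 and 4.71 in vehicle libraries 1 and 2 but 4.25 and 4.14 in vehicle libraries 3 and 4, inside the 3.70 to 4.36 of the auranofin libraries, and without the first pair the list was not called (median -0.12, adjusted p = 0.371). Adgre1 had 54.0 and 52.8 FPKM in vehicle libraries 3 and 4 and 65.2 in auranofin library 4. Marco, a scavenger receptor, had 6.12 ± 4.57 against 1.77 ± 0.802 FPKM. Markers of lipid-associated macrophages, which take up lipid in obese fat, fell (23 of 26 below 0, median -0.87, adjusted p = 5.07e-08), with Lipa, lysosomal lipase, at 70.3 ± 24.0 against 176 ± 95.6 FPKM and Atp6v0d2, a proton pump subunit, at 25.2 ± 13.5 against 89.3 ± 62.7 FPKM. Neutrophil and mast cell markers fell (13 of 14 below 0, median -0.81, adjusted p = 0.000190), with S100a8 at 7.06 ± 3.94 against 15.4 ± 5.70 FPKM and the mast cell tryptase Tpsb2 at 22.2 ± 9.21 against 77.9 ± 64.5 FPKM, and cytokine and chemokine genes fell (28 of 37 below 0, median -0.16, adjusted p = 0.0388), with Il1rn at 2.25 ± 1.34 against 9.01 ± 6.18 FPKM and Ccl2 at 14.1 ± 7.68 against 31.8 ± 19.3 FPKM. The cytokine list was not called without vehicle libraries 1 and 2 (median -0.053, adjusted p = 0.8291), while lipid-associated macrophage markers were (median -0.41). T and NK cell markers rose (20 of 23 above 0, median 0.34, adjusted p = 0.000229), with Cd3d of the T cell receptor complex at 1.41 ± 0.351 against 0.695 ± 0.369 FPKM and Gzma at 1.61 ± 0.386 against 0.779 ± 0.364 FPKM. Il7r had 5.53 ± 2.69 against 16.5 ± 10.2 FPKM. Each of these 5 lists had an adjusted p = 0.660 with an estimated correlation.

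Endothelial markers rose in eWAT (24 of 28 above 0, median 0.21, adjusted p = 0.00306), with Cldn5, of endothelial tight junctions, at 109.5 ± 12.5 against 60.8 ± 41.5 FPKM and Gpihbp1, which anchors lipoprotein lipase, at 57.3 ± 6.25 against 35.4 ± 16.5 FPKM, but not without vehicle libraries 1 and 2 (median -0.0085, adjusted p = 0.866). Epithelial and skin markers rose (9 of 9 above 0, median 0.30, adjusted p = 0.0284), with Krt18 at 2.45 ± 1.00 against 1.55 ± 0.684 FPKM. Hepatocyte markers rose (36 of 36 above 0, median 1.24, adjusted p = 1.75e-10), with Apoc3 at 9.60 ± 11.5 against 1.22 ± 0.708 FPKM and Apoc1, which macrophages also make, at 90.8 ± 32.9 against 45.9 ± 17.4 FPKM. Xenobiotic and bile-acid genes, typical of liver, rose beside them (13 of 15 above 0, median 0.40, adjusted p = 0.0151), with Por, which feeds electrons to cytochromes P450, at 68.3 ± 15.9 against 44.0 ± 12.5 FPKM. Each of the 4 lists had an adjusted p = 0.660 with an estimated correlation. Alb stood at 286 FPKM in auranofin library 2 and 113 in auranofin library 3, against 2.43 to 33.3 in the other libraries, and without auranofin library 2 the hepatocyte median was 0.77 and the xenobiotic list was not called (adjusted p = 0.318).

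No gene passed over all 13847 genes tested by limma in eWAT, where the smallest adjusted p was 0.429. At an unadjusted p under 0.05 there were 736 higher and 849 lower genes, and voom called 0. The groups did not overlap in 963 genes, 6.96% of those tested, against an average of 2.86% over all splits of the libraries. Nearest to the threshold were Eid2b, an inhibitor of differentiation (4.06 ± 0.340 against 2.30 ± 0.189 FPKM), Slc22a18 (5.33 ± 1.38 against 1.96 ± 0.813 FPKM) and Macrod1 (17.2 ± 4.38 against 8.24 ± 2.34 FPKM), higher in 4 of 4 auranofin libraries, and Adam12, a membrane protease (2.66 ± 0.821 against 5.87 ± 0.828 FPKM), Mical2, an actin regulator (1.53 ± 0.379 against 3.25 ± 0.566 FPKM), and Pvalb (0.917 ± 0.545 against 3.06 ± 0.665 FPKM), lower in 4 of 4. Adipoq had 2109 ± 695 against 1158 ± 428 FPKM (log2 change 0.89, SE 0.38, adjusted p = 0.429), Nqo1 had 3.72 ± 1.22 against 2.90 ± 0.289 FPKM, Mt1 had 127 ± 23.9 against 136 ± 34.4 FPKM and Mt2 had 1.72 ± 0.873 against 1.83 ± 1.06 FPKM. Of 35 lists tested, 10 were called higher and 7 lower, against 8 and 9 after quantile normalisation. No list member was called over all genes, and adjusted over the list alone 12 matrix and 20 cell cycle genes were lower and no member of the other 15 called lists passed.

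Several eWAT results rested on single libraries. Reads on ribosomal RNA genes made up 0.0796% to 0.643% of reads in genes with auranofin and 0.0134% to 0.214% with vehicle. In vehicle library 2, mitochondrial transcripts made up 8.11% of reads, against 3.5002% to 3.7155% in the other vehicle libraries. In auranofin library 1 the slope of log2 expression per doubling of gene length was -0.130, against -0.0267 to -0.0120 in the other auranofin libraries. Without vehicle library 2 and auranofin library 1, an alternative chosen after the data were seen, limma called 1 gene and 18 lists, 7 higher and 11 lower. That gene was Trbj2-5, a joining segment of the T cell receptor, chosen here after its values were seen, which was also the 1 gene called without auranofin library 1 alone. Sample quality weights called 6 genes and 1 fit of all libraries 1280 (491 higher, 789 lower). The lipolysis list lost its call without vehicle library 1 (adjusted p = 0.184), auranofin 1 (0.0883) or auranofin 2 (0.0739), and the fatty acid oxidation list without the same libraries (0.151, 0.142 and 0.0659). The cytokine list lost it without vehicle 1 (0.680), vehicle 3 (0.0523), auranofin 1 (0.0766) or auranofin 2 (0.0781), and the thioredoxin list without vehicle 3 (0.0775), vehicle 4 (0.0637) or auranofin 1 (0.379). The endothelial list lost it without vehicle 1 (0.155) and the epithelial list without vehicle 4 (0.136) or auranofin 3 (0.268). Without vehicle library 1 the medians were 0.31 for mature adipocyte genes and -0.30 for macrophage markers, and without vehicle library 2 they were 0.20 for lipolysis and -0.40 for matrix genes. Endothelial markers stood at 0.38 without vehicle 3 and 0.41 without auranofin 1, cytokines at -0.25 without vehicle 4, and oxidative phosphorylation at 0.22 without auranofin 1. Without auranofin 2, matrix genes stood at -0.37 and lipid-associated macrophage markers at -0.53, and without auranofin 3 the thioredoxin list stood at 0.24 and T and NK cell markers at 0.19. The TPM scale ended the calls of the thioredoxin, cytokine and fibroblast lists, and quantile normalisation those of the lipolysis and thioredoxin lists. Removal of the gene-length trend ended the thioredoxin (0.0901) and epithelial calls (0.120), a pseudocount of 0.1 the cytokine call (0.0505), and no filter the lipolysis (0.0540) and epithelial calls (0.0734). Without vehicle 2 and auranofin 1 together, the mature adipocyte (0.0744), lipolysis (0.102), fatty acid oxidation (0.0855) and thioredoxin lists (0.510) were not called.

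In BAT, where the question was which transcripts differed in a thermogenic depot, 3 genes passed and all were lower after auranofin. Timp1 (ENSMUSG00000001131, chromosome X, 20870166 to 20874735), a secreted inhibitor of matrix proteases, fell from 5.80 ± 1.10 FPKM with vehicle to 0.787 ± 0.352 with auranofin (log2 change -1.94, SE 0.17, limma adjusted p = 0.0160), 13.6% of the vehicle level. Csf2rb (ENSMUSG00000071713, chromosome 15, 78325752 to 78353847), the beta chain shared by the receptors of GM-CSF, IL-3 and IL-5, fell from 6.46 ± 0.480 to 3.09 ± 0.303 FPKM (log2 change -0.87, SE 0.085, adjusted p = 0.0187). Iigp1 (ENSMUSG00000054072, chromosome 18, 60376029 to 60392627), an interferon-inducible GTPase, fell from 11.1 ± 0.681 to 5.74 ± 0.537 FPKM (log2 change -0.84, SE 0.085, adjusted p = 0.0187). Each was lower in 4 of 4 auranofin libraries with no overlap between groups. The mouse genome holds close relatives of the last pair, so how reads were divided between copies is uncertain. Csf2rb2, the near-identical neighbour of Csf2rb, had 0.488 ± 0.239 against 0.900 ± 0.140 FPKM.

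**Figure D3:**
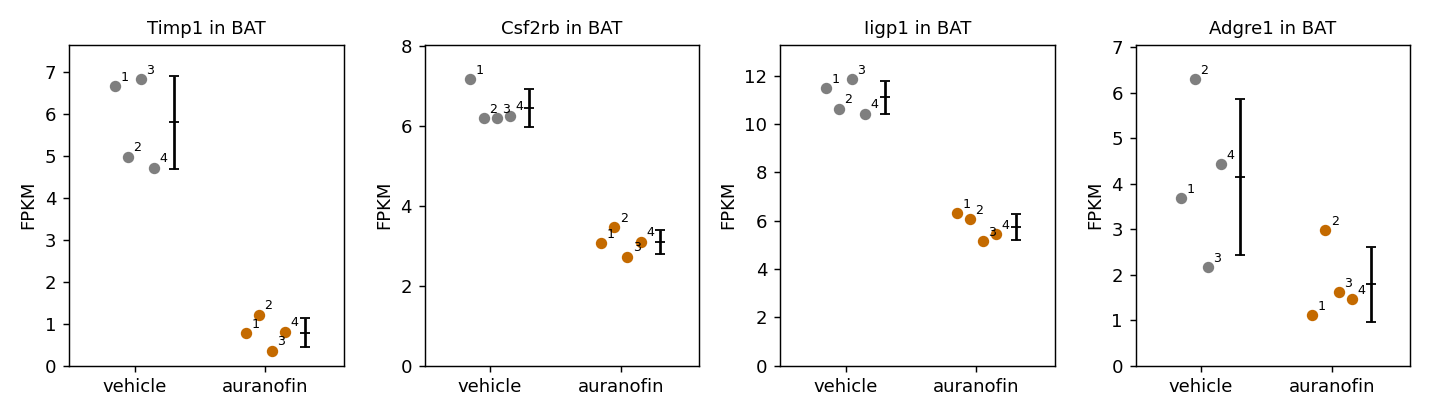
FPKM (y axis) of Timp1, Csf2rb, Iigp1 and Adgre1 in the 8 BAT libraries, with the mean and SD of each group of 4. Timp1, Csf2rb and Iigp1 were lower in all 4 auranofin libraries than in any vehicle library, and Adgre1 had 1.79 ± 0.823 against 4.15 ± 1.72 FPKM.

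Matrix genes fell as a group in BAT (42 of 43 below 0, median -0.68, camera adjusted p = 5.77e-28; adjusted p = 0.258 with an estimated correlation). Over all genes 1 member, Timp1, was called lower, and adjusted over the list alone 27 were lower. Tnc, the matrix protein tenascin C, had 0.999 ± 0.686 FPKM with auranofin against 3.42 ± 0.629 with vehicle (log2 change -1.19, SE 0.21), Col6a3 had 5.15 ± 1.87 against 11.1 ± 1.70 FPKM and Lum had 5.22 ± 0.766 against 9.74 ± 1.82 FPKM. Fibroblast and progenitor markers fell (22 of 24 below 0, median -0.31, adjusted p = 6.10e-08; adjusted p = 0.258 with an estimated correlation), with 0 called over all genes and 6 lower adjusted over the list alone. Lox, a collagen cross-linker, had 8.22 ± 3.00 against 16.2 ± 1.97 FPKM and Thy1 had 3.40 ± 0.851 against 6.21 ± 1.07 FPKM.

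Inflammatory genes fell in BAT. Of 34 cytokine and chemokine genes 33 were below 0 (median -0.33, adjusted p = 1.83e-16; adjusted p = 0.207 with an estimated correlation), with 0 called over all genes and 13 lower adjusted over the list alone. Csf1, the growth factor of macrophages, had 4.84 ± 2.32 against 14.5 ± 2.64 FPKM (log2 change -1.47, SE 0.24), Ccl2, a monocyte attractant, had 6.03 ± 5.26 against 24.4 ± 3.70 FPKM (log2 change -2.08, SE 0.38) and Cxcl2 had 0.240 ± 0.133 against 1.26 ± 0.490 FPKM. Macrophage markers fell (22 of 23 below 0, median -0.59, adjusted p = 2.33e-14), with 16 lower adjusted over the list alone. Cd68 had 8.42 ± 3.42 against 19.8 ± 5.26 FPKM, Adgre1 had 1.79 ± 0.823 against 4.15 ± 1.72 FPKM and Lgals3, or galectin 3, had 16.4 ± 9.09 against 50.1 ± 8.21 FPKM (log2 change -1.67, SE 0.30). Lipid-associated macrophage markers fell (23 of 25 below 0, median -0.48, adjusted p = 1.96e-10), with 12 lower adjusted over the list alone, among them Capg at 4.79 ± 1.82 against 10.9 ± 1.16 FPKM and Ctss, a lysosomal protease, at 14.5 ± 5.41 against 33.1 ± 8.65 FPKM. Acute-phase and complement genes fell (13 of 16 below 0, median -0.62, adjusted p = 2.55e-05), with 8 lower adjusted over the list alone, among them Il1r1, the IL-1 receptor, at 2.61 ± 0.989 against 6.53 ± 1.21 FPKM, Stat3 at 8.07 ± 1.83 against 14.0 ± 1.49 FPKM and C4b at 5.91 ± 2.39 against 12.5 ± 1.435 FPKM. No member of these 3 lists was called over all genes, and for each the adjusted p = 0.258 with an estimated correlation.

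Interferon-stimulated genes fell in BAT (30 of 34 below 0, median -0.14, adjusted p = 1.84e-05), with Iigp1 the 1 member called over all genes and the 1 lower adjusted over the list alone. Igtp had 6.78 ± 0.834 against 8.95 ± 0.630 FPKM. Immediate-early genes fell (27 of 30 below 0, median -0.61, adjusted p = 5.84e-09), with 0 called over all genes and 5 lower adjusted over the list alone. Fosl1, a subunit of the AP-1 factor, had 2.78 ± 0.493 against 9.24 ± 2.64 FPKM (log2 change -1.41, SE 0.19, adjusted p = 0.0999), Myc had 4.26 ± 3.39 against 11.6 ± 2.70 FPKM and Klf6 had 17.9 ± 4.23 against 28.1 ± 5.16 FPKM. Adipokines fell (13 of 20 below 0, median -0.31, adjusted p = 0.00358), with 0 called over all genes and 5 lower adjusted over the list alone, among them Rarres2, or chemerin, at 19.6 ± 5.88 against 32.9 ± 5.25 FPKM, and Sncg at 129 ± 56.4 against 252 ± 45.9 FPKM. Cell cycle genes fell (16 of 21 below 0, median -0.12, adjusted p = 0.00439), with 0 called either way and Rrm2 at 0.320 ± 0.119 against 0.741 ± 0.0893 FPKM. For each of these 4 lists the adjusted p = 0.301 with an estimated correlation. The stress response list had a median of -0.090 (26 of 40 below 0, adjusted p = 0.0231; adjusted p = 0.574 with an estimated correlation), with 0 called either way and Xbp1 at 21.1 ± 3.95 against 27.8 ± 2.17 FPKM.

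In all, 6 lists rose in BAT: oxidative phosphorylation, mitochondrially encoded transcripts, lipogenesis, thermogenic, circadian and xenobiotic genes. Those of fatty acid oxidation (median 0.087, adjusted p = 0.137), lipolysis (median 0.037, adjusted p = 0.992) and mature adipocyte genes (median 0.13, adjusted p = 0.0864) were not called. Oxidative phosphorylation genes had 67 of 70 above 0 (median 0.24, adjusted p = 1.41e-07; adjusted p = 0.580 with an estimated correlation), with Atp5j at 63.8 ± 11.8 against 48.2 ± 2.96 FPKM. Short genes were higher in BAT, as in eWAT. The median log2 change ran from 0.182 for protein-coding genes of 500 to 1000 nt to -0.0197 for those over 6000 nt (Spearman correlation of change with length -0.205). With that trend removed, chosen after the data were seen, the oxidative phosphorylation median was 0.18 and still called. All 13 mitochondrially encoded transcripts were above 0 (median 0.25, adjusted p = 0.0289). Lipogenesis genes had 19 of 22 above 0 (median 0.21, adjusted p = 0.0284), with Thrsp, a lipogenic factor, at 1455 ± 256 against 995 ± 177 FPKM; both had an adjusted p = 0.581 with an estimated correlation. Thermogenic genes had a median of 0.24 (18 of 25 above 0, adjusted p = 0.0386; adjusted p = 0.385 with an estimated correlation), with Cidea, a lipid droplet protein, at 2049.6 ± 369.6 against 1431 ± 99.6 FPKM and Dio2, which activates thyroid hormone, at 21.8 ± 6.23 against 14.1 ± 3.48 FPKM. Ucp1 had 3129 ± 786 against 2506 ± 552 FPKM (log2 change 0.32, SE 0.24, adjusted p = 0.647). Circadian clock genes rose (14 of 19 above 0, median 0.22, adjusted p = 0.0407; adjusted p = 0.258 with an estimated correlation), with Dbp at 4.64 ± 2.83 against 1.64 ± 0.556 FPKM, and xenobiotic genes rose (7 of 8 above 0, median 0.23, adjusted p = 0.0341; adjusted p = 0.301 with an estimated correlation), with Cyp1a1, a target of the aryl hydrocarbon receptor, at 12.97 ± 4.75 against 4.53 ± 2.95 FPKM. Of these 6 lists no member was called over all genes, and adjusted over the list alone Cyp1a1 was the 1 member higher.

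Limma tested 13067 genes in BAT. At an unadjusted p under 0.05 there were 609 higher and 850 lower, the 3 called among them, and voom called 4 genes, these and Pvr. The groups did not overlap in 697 genes, 5.33% of those tested, against 2.86% by chance. Just short of the threshold were Pvr, an adhesion receptor (3.90 ± 0.516 against 7.19 ± 0.287 FPKM, adjusted p = 0.0584), Irgm2, an interferon-inducible GTPase whose annotated span overlaps that of Igtp (4.41 ± 0.239 against 6.79 ± 0.121 FPKM, adjusted p = 0.0812), and on the higher side Coro6 (12.2 ± 1.117 against 6.66 ± 0.993 FPKM) and Med29, of the mediator complex (11.2 ± 0.787 against 7.39 ± 0.376 FPKM), both with an adjusted p = 0.0999. Adipoq had 621 ± 93.4 against 618 ± 84.7 FPKM, with a log2 change of 0.0046 that turned to -0.093 after quantile normalisation, and Nqo1 had 1.48 ± 0.168 against 1.48 ± 0.312 FPKM, with a change of 0.0095. Txnrd1 had 13.4 ± 0.857 against 14.8 ± 1.38 FPKM (log2 change -0.13, SE 0.090), Mt1 had 237 ± 142 against 277 ± 122 FPKM and Mt2 had 1.27 ± 1.07 against 3.21 ± 1.35 FPKM (log2 change -0.97, SE 0.36, adjusted p = 0.385). Skeletal muscle markers had a median of 0.67 (35 of 36 above 0) and were not called (adjusted p = 0.0557), with mean log2 levels of 5.51 and 4.48 in auranofin libraries 2 and 4 and 2.94 and 3.83 in vehicle libraries 3 and 4, against 0.826 to 1.64 in the others. Endothelial markers had a median of 0.053 (adjusted p = 0.410).

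Of the 32 lists tested in BAT, 6 were called higher and 11 lower, against 4 and 12 after quantile normalisation. The 3 gene calls rested on most of the libraries. No gene was called with replicate number as a block or without vehicle 1, 3 or 4 or auranofin 1 or 4. Timp1 alone was called without auranofin 3 or on the TPM scale, and Timp1 and Fosl1 without vehicle 2. Without auranofin 2, which had the highest muscle mean, 208 genes were called (21 higher, 187 lower). A fit of all 32 libraries called 96 (9 higher, 87 lower), sample quality weights 6 and an adjusted p under 0.1 gave 9. With the muscle mean as a covariate, chosen after the data were seen, 15 genes were lower. The thermogenic list lost its call without vehicle library 2 (adjusted p = 0.0604), vehicle 3 (0.1001), vehicle 4 (0.142), auranofin 1 (0.0829), auranofin 2 (0.0652) or auranofin 4 (0.0503), and the lipogenesis list without vehicle 1 (0.118), vehicle 2 (0.0729), auranofin 1 (0.0592) or auranofin 3 (0.297). Mitochondrially encoded transcripts lost it without vehicle 2 (0.184), vehicle 3 (0.0873), auranofin 1 (0.191) or auranofin 3 (0.279), and the stress response list without vehicle 2 (0.0958), vehicle 3 (0.0852) or auranofin 4 (0.259). Xenobiotic genes lost it without vehicle 1 (0.0510), vehicle 3 (0.0873), auranofin 2 (0.122) or auranofin 4 (0.195), circadian genes without vehicle 1 (0.0514), vehicle 2 (0.0517), vehicle 3 (0.0800) or auranofin 2 (0.125), and cell cycle genes without vehicle 2 (0.0632). That left 11 lists without vehicle library 2. Medians moved to -0.20 and -0.20 for adipokines without vehicle 2 or 3, to -0.090, -0.26 and -0.083 for interferon-stimulated genes without vehicle 2, auranofin 1 or auranofin 4, and to -0.40 for immediate-early genes without auranofin 3. They moved to 0.12 and 0.36 for oxidative phosphorylation without vehicle 4 or auranofin 2, to 0.36 and 0.37 for lipogenesis without vehicle 3 or auranofin 4, and to 0.11 for circadian genes without auranofin 1. Quantile normalisation ended the calls of the thermogenic, lipogenesis and mitochondrially encoded lists, and removal of the gene-length trend the last (0.105). The muscle covariate ended those of the stress response (0.0772), xenobiotic (0.0772) and circadian lists (0.0620). No filter ended the thermogenic (0.0540), xenobiotic (0.729) and circadian calls (0.115), and a pseudocount of 0.1 the thermogenic call (0.0552).

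In liver, the macrophage list rose and the interferon, antioxidant and fatty acid oxidation lists fell, but 26 of 35 splits called as many. Macrophage markers rose (25 of 26 above 0, median 0.31, adjusted p = 5.25e-09; adjusted p = 0.507 with an estimated correlation). Csf1r, the CSF1 receptor, had 11.8 ± 2.24 FPKM with auranofin against 7.75 ± 1.78 with vehicle (log2 change 0.56, SE 0.17), Cd68 had 7.97 ± 1.35 against 5.39 ± 0.862 FPKM and Adgre1 had 4.24 ± 0.749 against 3.201 ± 0.914 FPKM. B cell markers rose (11 of 13 above 0, median 0.29, adjusted p = 0.000369), with Igkc, the kappa light chain, at 40.5 ± 15.3 against 24.4 ± 4.32 FPKM, and mesothelial markers, of the cells that cover the organ, rose (6 of 10 above 0, median 0.35, adjusted p = 0.00111), with Upk3b at 1.19 ± 0.333 against 0.281 ± 0.231 FPKM and Msln at 1.47 ± 0.736 against 0.396 ± 0.249 FPKM. The last pair of lists had an adjusted p = 0.204 with an estimated correlation.

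Interferon-stimulated genes fell in liver (28 of 35 below 0, median -0.20, adjusted p = 8.09e-07; adjusted p = 0.357 with an estimated correlation). Ifit3b had 0.704 ± 0.207 against 1.61 ± 0.127 FPKM (log2 change -0.62, SE 0.11), and its near-identical copy Ifit3 had 6.49 ± 1.57 against 7.76 ± 0.816 FPKM. Rsad2, the antiviral protein viperin, had 1.11 ± 0.354 against 2.18 ± 0.286 FPKM, Tap1, a peptide transporter, had 6.28 ± 0.789 against 8.41 ± 0.307 FPKM and Usp18, which damps interferon signals, had 2.74 ± 0.257 against 3.99 ± 0.578 FPKM. Fatty acid oxidation genes and PPAR-alpha targets fell (31 of 39 below 0, median -0.16, adjusted p = 6.34e-06; adjusted p = 0.507 with an estimated correlation), with Plin2 at 251 ± 50.3 against 367 ± 25.5 FPKM (log2 change -0.57, SE 0.14) and Vnn1 at 65.5 ± 7.61 against 81.4 ± 8.75 FPKM. NRF2 targets fell (33 of 40 below 0, median -0.14, adjusted p = 0.000369), with Aldh1a1, a retinal dehydrogenase, at 473 ± 76.3 against 642 ± 50.1 FPKM and Gstm4, a glutathione transferase, at 47.1 ± 4.82 against 59.9 ± 7.44 FPKM. The thioredoxin and selenoprotein list fell (26 of 35 below 0, median -0.075, adjusted p = 0.0251), with Dio1, a selenoprotein that activates thyroid hormone, at 89.2 ± 9.89 against 130.4 ± 19.6 FPKM (log2 change -0.54, SE 0.12) and Selenop, the selenium carrier of plasma, at 1669 ± 63.6 against 2002 ± 201 FPKM. Selenom had 2.64 ± 0.225 against 1.66 ± 0.240 FPKM. Both had an adjusted p = 0.555 with an estimated correlation. Txnrd1 had 27.4 ± 3.74 against 30.2 ± 3.08 FPKM (log2 change -0.14, SE 0.11, adjusted p = 0.850), Nqo1 had 7.33 ± 2.06 against 8.20 ± 0.404 FPKM and Mt1 had 33.2 ± 5.64 against 42.2 ± 48.9 FPKM.

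No gene passed over all 13122 genes tested by limma in liver, where the smallest adjusted p was 0.0824. At an unadjusted p under 0.05 there were 328 higher and 465 lower genes, and voom called 0. The groups did not overlap in 488 genes, 3.72% of those tested, against 2.86% by chance. Nearest to the threshold by the naming rule were Lpgat1, a lipid acyltransferase (23.3 ± 0.562 against 30.7 ± 1.46 FPKM), Hist1h1c, a linker histone (46.2 ± 7.05 against 72.1 ± 9.36 FPKM), and Qsox1 (39.9 ± 3.70 against 54.4 ± 5.16 FPKM), lower in 4 of 4 auranofin libraries, and Fmo2, a monooxygenase (3.84 ± 0.467 against 2.18 ± 0.339 FPKM), and Ppl (5.77 ± 0.820 against 3.65 ± 0.373 FPKM), higher in 4 of 4, with adjusted p from 0.509 to 0.756. Of 35 lists tested, 3 were called higher and 4 lower. No list member was called over all genes; adjusted over the list alone 4 interferon-stimulated genes were lower, 4 mesothelial markers higher and 1 member of the thioredoxin list higher and 1 lower, with none in the other 4 called lists. The NRF2 list lost its call without vehicle library 2 (adjusted p = 0.0580), and the thioredoxin list without vehicle 3 (0.0528), auranofin 1 (0.0707), auranofin 2 (0.105) or auranofin 4 (0.0758) and after quantile normalisation (0.222). Medians moved to 0.47 for macrophage markers without vehicle 3, to -0.12 for the thioredoxin list without auranofin 3 and to -0.11 for fatty acid oxidation without auranofin 4. Without vehicle library 4, 13 lists were called. Gm23354 was the 1 gene called without auranofin library 4, with sample quality weights or at an adjusted p under 0.1, Gm10029 the 1 called with no filter, and Gm23887, Mir709 and Mir3075 the 3 called, all higher, without auranofin libraries 1 and 3; these were chosen after their values were seen, and the last alternative was added after the data were seen. Without those 2 libraries mesothelial markers were not called (adjusted p = 0.0780). A fit of all libraries called 25 (9 higher, 16 lower).

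**Figure D4:**
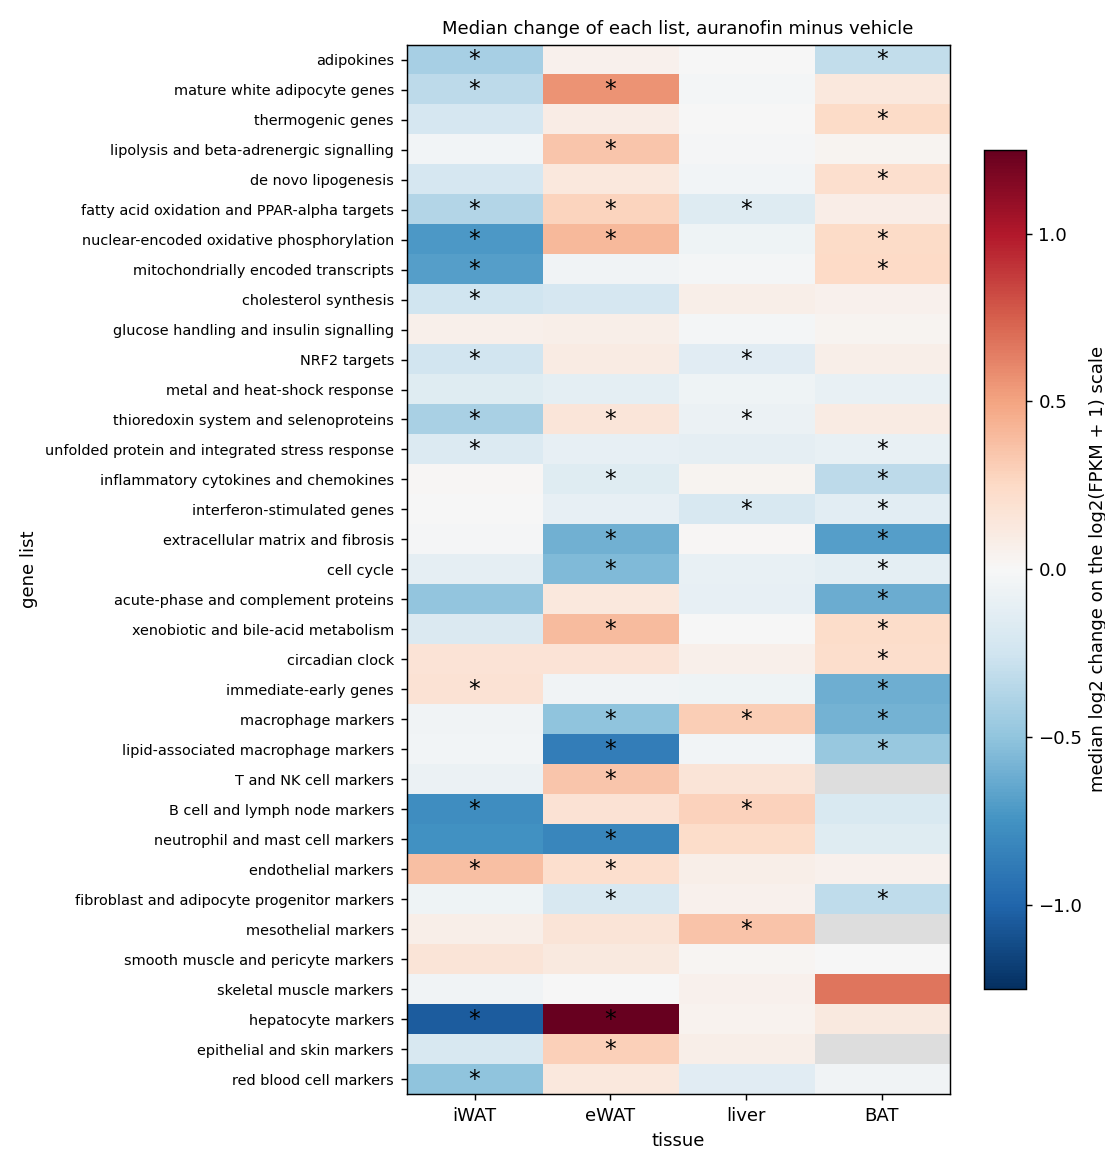
Median log2 change of each gene list (y axis) in the 4 tissues (x axis) as colour, with a star where camera's adjusted p was under 0.05 and grey where fewer than 5 members were measured. Oxidative phosphorylation has a median of -0.72 in iWAT and 0.41 in eWAT, and the iWAT medians of mature adipocyte genes (-0.33) and the stress response (-0.17) turn to 0.17 and 0.040 after quantile normalisation.

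Whether a change differed between tissues was tested directly. Between iWAT and BAT, 3 of 13372 genes differed, all with a higher change in iWAT. Fosl1 (chromosome 19, 5447703 to 5455945) differed by 2.005 (SE 0.29, limma adjusted p = 0.0397), with changes of 0.60 in iWAT and -1.41 in BAT. Irgm2 (chromosome 11, 58199618 to 58222782) differed by 0.85 (SE 0.13, adjusted p = 0.0397), with 0.32 and -0.53. Csf1 (chromosome 3, 107741048 to 107760469) differed by 1.85 (SE 0.29, adjusted p = 0.0467), with 0.38 and -1.47. At an unadjusted p under 0.05 there were 3093 genes. Just short of the threshold were Csf2rb, which differed by 1.442 (adjusted p = 0.0650), and Tnc, by 1.49. Leaving out vehicle 1, 3 or 4 or auranofin 1, 3 or 4 in both tissues gave 0 genes, vehicle 2 gave 1 (Fosl1) and auranofin 2 gave 3870, and an adjusted p under 0.1 gave 29 (24 larger in iWAT, 5 smaller).

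Limma called 0 genes between eWAT and iWAT (13670 tested, 3219 at an unadjusted p under 0.05, smallest adjusted p 0.177). Retn, 1 of the 5 genes with the smallest p among those higher in eWAT, had changes of 1.17 in eWAT and -0.92 in iWAT (difference 2.08, SE 0.44). Leaving out auranofin 2 in both depots gave 1829 genes and leaving out vehicle 2 gave 1, Snord83b. Between eWAT and BAT it called 0 of 13842 (809 at an unadjusted p under 0.05), with Pvr at a difference of 0.90 (adjusted p = 0.138); 1 gene was called without auranofin 2, Thbs1, and 1 with no filter, Gm19510. Between liver and the mean of the fat depots it called 0 of 14413 (870 at an unadjusted p under 0.05, smallest adjusted p 0.0995). There, 46 genes were called with no filter (20 higher, 26 lower in liver) and 2 at an adjusted p under 0.1, Gm35696 and Gm23354. Leaving out vehicle 2 gave 1 (Gm35696), vehicle 4 gave 1 (Saa1), auranofin 4 gave 1 (Chrna4) and auranofin 3 gave 3 (Mppe1, Gm40923 and Tmem28). The genes named for these single settings were chosen after their values were seen. Voom was not run on the differences.

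Changes were compared across genes between tissues, where genes are not independent replicates. Of the 6 pairs, eWAT and BAT had the highest correlation of log2 changes (Pearson 0.38, Spearman 0.399, 12096 genes), which ran from 0.264 without BAT vehicle library 4 to 0.479 without BAT auranofin library 3. At an unadjusted p under 0.05, 205 genes were lower in both, against 42.35 if the lists were independent, 61 were higher in both against 28.76, and 14 went opposite ways against 71.86. The lists called lower in both were cytokines and chemokines, extracellular matrix, cell cycle, macrophage, lipid-associated macrophage and fibroblast markers. Oxidative phosphorylation and xenobiotic genes were called higher in both. Of these, the eWAT calls of cytokines, macrophage and fibroblast markers ended without eWAT vehicle libraries 1 and 2. With an estimated correlation none of these lists was called in either tissue. The xenobiotic call ended without eWAT auranofin library 2, which had the highest Alb in eWAT, and in BAT with the muscle covariate or without vehicle 1, vehicle 3, auranofin 2 or auranofin 4. In iWAT and eWAT the Spearman correlation was -0.149 (12708 genes), and it turned to 0.0846 without eWAT auranofin library 1. It was 0.20 between iWAT and liver (11081 genes, 0.113 to 0.289 with 1 library left out), -0.158 between iWAT and BAT (-0.196 to -0.0583, the last without BAT vehicle library 4), -0.0474 between eWAT and liver (turning to 0.0344, the highest, without liver vehicle library 3) and 0.0451 between liver and BAT (turning to -0.068 without liver auranofin library 3). The correlation of change with gene length was -0.237 in eWAT and -0.205 in BAT but 0.36 in iWAT and 0.00502 in liver. With the length trend removed, an alternative chosen after the data were seen, the Spearman correlation was 0.359 between eWAT and BAT, -0.0506 between iWAT and eWAT and -0.0946 between iWAT and BAT. No gene was called in more than 1 tissue.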

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

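Of the tests below, those for a swap, for a gene length trend in iWAT, for lists matched on length and abundance, and for the share of brown adipocytes were chosen after the results were seen. The test of that share by the endothelial list was set after a test of the difference of endothelial from macrophage markers, in which auranofin library 2 overlapped the vehicle libraries (exact permutation p = 0.0571).

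Single libraries far from the other members of their group of 4 were found in 22 of 224 groups of values, where chance gives about 1 in 20, or 11.2. The figure given for each is the gap to the nearest library as a share of the whole range. In iWAT vehicle libraries, library 4 had a skeletal muscle mean of 4.48 against 0.935 to 1.01 in the others (0.979), and library 1 had log2 Alb of 7.77 (0.839). In iWAT auranofin libraries, library 2 had reads on 19949 genes (0.87), Lep at 11.11 against 10.02 to 10.19 (0.839), Nqo1 at 1.89 (0.889) and Gtf2f2 at 3.54 (0.951) on the log2 scale, and library 4 had a muscle mean of 3.75 (0.899).

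In eWAT vehicle libraries, library 4 had fewer reads in genes (16126312, 0.955). Library 2 had 8.11% mitochondrial reads (0.953) and Msln, a mesothelial marker, at 1.71 FPKM (0.983), and library 1 had Mical2 at 2.35 on the log2 scale (0.929). In eWAT auranofin libraries, library 1 had a slope on gene length of -0.130 (0.876) and library 3 had log2 Msln of 4.52 (0.849). In liver, Mt2 was above 0 in vehicle library 3 alone among the vehicle libraries (1), auranofin library 3 had reads on 18970 genes (0.902) and an oxidative phosphorylation mean of 6.84 (0.852), and auranofin library 4 had log2 Hist1h1c of 5.20 (0.855). In BAT vehicle libraries, library 4 had 23.0% mitochondrial reads (0.882), library 2 had log2 Alb of 0.855 (0.849) and library 1 had log2 Csf2rb of 3.03 (0.931). In BAT auranofin libraries, library 2 had a macrophage mean of 2.04 (0.885) and library 4 had log2 Grk3 of 3.86 (0.898).

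The changes of Fosl1, Irgm2 and Csf1 differed between iWAT and BAT in the test of the difference itself, by 2.005, 0.85 and 1.85 on the log2 scale.

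In iWAT, auranofin library 2 lay with the vehicle libraries (mean distance 41.14, against 68.82 to the other auranofin libraries), while oxidative phosphorylation transcripts were lower in the others. The tables argue against a swap within iWAT, since 0 vehicle libraries lay nearer to auranofin libraries 1, 3 and 4 than to the other vehicle libraries, and against a gene length trend as the whole cause, since 4287 genes were called without library 2 after its removal against 4819 before. Gene length and abundance stay open as the whole cause of the list's change. Its median of -0.72 lay at percentile 0 of 10000 matched lists (middle 95% -0.52 to -0.37). Members vary together, so such lists understate the spread and cannot decide it. A single wrong label stays open, since library 2 lay beyond 3 vehicle libraries in 18.8% of the genes that part the other auranofin libraries from them (mean over the 4 sets of 3, against all 4 it was 11.91%), within the 14.34% to 48.41% of vehicle libraries held out from the same sets. An animal that did not respond to auranofin, or a difference in RNA quality or in handling of the tissue, stays open too and was not tested, though reads on ribosomal RNA genes parted the libraries the same way.

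In BAT, macrophage, cytokine and matrix lists were lower after auranofin. The tables argue against skeletal muscle carried along, since the macrophage median was -0.60 with the muscle mean as a covariate and -0.59 without, and against a gene length trend, since the matrix median was -0.70 after its removal and -0.68 before. For macrophage and matrix genes they argue against a higher share of brown adipocytes that dilutes all other cell types alike as the whole cause. Such a dilution would lower endothelial markers by about as much, and their median was 0.053 with an SD of 0.225 over 26 members. Their mean level was 3.78 to 3.996 in the auranofin libraries and 3.83 ± 0.0959 with vehicle, where the macrophage change would need 3.24 and the matrix change 3.15. A rise of endothelial cells at the same time, and an effect of auranofin on macrophages or fibroblasts, stay open as hypotheses that were not tested.

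Hepatocyte transcripts were high in single white fat libraries. In eWAT auranofin library 2, 83.1% of 148 genes abundant in liver lay within 2-fold of a common share of their liver level (median 0.779%, Alb 286 FPKM or 0.603%), as RNA carried along from liver would give. The share was 86.5% in iWAT vehicle library 1 and 83.1% in eWAT auranofin library 3. Where such RNA may have entered is not known from these data, and no biological explanation was tested.

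Other splits of the same libraries were counted for each number of genes and lists. In BAT, 1 of 35 splits (the least possible, the real one) gave 3 genes (highest other 2), so chance is not excluded. Where the real count was 0, each split gives at least as many, so the splits say nothing of chance: 35 of 35 in iWAT, eWAT (highest other 2) and liver (highest other 2). For the lists chance is not excluded. Of 35 splits, 16 gave as many as 14 in iWAT (highest other 20) and 15 as many as 17 in eWAT (highest other 21). In liver 26 gave as many as 7 (highest other 15) and in BAT 3 as many as 17 (highest other 19). The split highest in genes in iWAT, with vehicle 3 in place of auranofin 2, called 2526 genes, which points to a structure of the samples that differs from the treatment groups. Of 100 drawn splits per interaction, 4 gave as many as 3 genes between iWAT and BAT (highest other 759), so chance is not excluded. The split with 759 put iWAT auranofin 2 with vehicle 1, 3 and 4 and vehicle 2 with the other auranofin libraries, which points to the same structure. For the other interactions the real count was 0, so the splits say nothing of chance. The highest others were 3 between eWAT and iWAT, 29 between eWAT and BAT and 24 between liver and fat.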

How the results depend on the processing

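Removal of a gene-length trend, the skeletal muscle covariate, pairs of libraries left out, the TPM scale for lists, and libraries left out of the tissue correlations were chosen after the data were seen. For every result below the cause of a difference was not tested, except where fewer libraries or genes or a looser threshold is the alternative itself. Of the results and settings tried, 6958 kept direction and side of the threshold or stayed close, 271 no longer passed, 259 newly passed, 84 moved and 46 reversed.

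With each list's correlation estimated, 0 lists were called in any tissue. Fry called 2 in BAT, the circadian clock list (higher) and the cytokine list (lower). Sample quality weights called 6095 genes in iWAT, 6 in eWAT, 1 in liver and 6 in BAT, and took Lep in iWAT to -0.53, past the threshold. A fit of all libraries called 722, 1280, 25 and 96 genes. An adjusted p under 0.1 gave 1 gene in liver, 9 in BAT, 29 between iWAT and BAT and 2 between liver and fat. No filter gave 1 gene in liver, 1 between eWAT and BAT and 46 between liver and fat. A pseudocount of 0.1 took Lep in liver to -0.087. In BAT the TPM scale called 1 gene and the muscle covariate 15. Without the doubted pair, eWAT had 1 gene and liver 3 genes and 12 lists. Without vehicle 1 and 2, which stood apart, eWAT had 15 lists, with 7 of the 17 lists no longer called.

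With replicate number as a block, BAT had 0 genes, iWAT and BAT differed in 2, and the other gene counts were the same. The immediate-early list in iWAT (adjusted p = 0.0573) and the lipolysis list in eWAT (0.0611) were not called. The libraries were not taken as pairs, since in no tissue were all 4 correlations of same-numbered vehicle and auranofin libraries over 0.1. These ran from -0.218 to 0.397, with 7 of 16 over 0.1, and in iWAT all were above 0 (0.0695, 0.161, 0.279 and 0.397). Of 8 libraries per tissue, 5 in iWAT, 0 in eWAT, 4 in liver and 1 in BAT correlated best with their own number. Correlations of the same label across tissues ran from -0.375 to 0.354, with 15 of 48 over 0.1.

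On the TPM scale, which moved the median of all genes to 0.234 in iWAT and -0.0973 in BAT, Mt1 in iWAT (0.24), Adipoq in BAT (-0.14) and Nqo1 in BAT (-0.092) changed sign with that shift. The direction reversed in iWAT for Mt1 after quantile normalisation (0.29) and with the length trend removed (0.25). Quantile normalisation also reversed Lep (0.032) and Adipoq (0.15), the mature adipocyte list (0.17), the NRF2 list (-0.0040, where the median kept its sign and the test did not) and the stress response list (0.040). Removal of the length trend reversed Txnrd1 (-0.023) and Mt2 (0.16). In eWAT, Mt2 reversed with voom (0.012) and without the doubted pair (0.085). In BAT, Adipoq reversed with median ratios (-0.0017), quantile normalisation (-0.093), quality weights (-0.057), the length trend removed (-0.078) and the muscle covariate (-0.013), and Nqo1 with quality weights (-0.029) and the length trend removed (-0.066). None of these genes had passed the threshold.

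With 1 library left out in turn, genes called ran from 0 to 4819 in iWAT (4819 without auranofin 2), 0 to 1 in eWAT (1 without auranofin 1), 0 to 1 in liver (1 without auranofin 4) and 0 to 208 in BAT (208 without auranofin 2). Lists ran from 11 to 16 in iWAT, 13 to 20 in eWAT, 6 to 13 in liver (13 without vehicle 4) and 11 to 18 in BAT (11 without vehicle 2). Genes that differed between tissues ran from 0 to 1829 for eWAT and iWAT, 0 to 1 for eWAT and BAT, 0 to 3870 for iWAT and BAT and 0 to 3 for liver and fat, the first 3 highest without auranofin 2 and the last without auranofin 3. Lep ran from -0.60 to -0.24 in iWAT and -0.53 to 0.12 in eWAT. Adipoq in BAT ran from -0.097 to 0.11, Nqo1 from -0.048 to 0.22 in iWAT and -0.057 to 0.077 in BAT, Mt1 from -0.33 to 0.31 in iWAT, -0.23 to 0.043 in eWAT and -0.16 to 0.96 in liver, and Mt2 from -0.44 to 0.12 in iWAT and -0.27 to 0.18 in eWAT. Correlations between tissues ran from -0.255 to 0.0846 for iWAT and eWAT, 0.113 to 0.289 for iWAT and liver, -0.196 to -0.0583 for iWAT and BAT, -0.115 to 0.0344 for eWAT and liver, 0.264 to 0.479 for eWAT and BAT and -0.068 to 0.0953 for liver and BAT. Removal of the length trend took those of iWAT and eWAT to -0.0506 and of iWAT and BAT to -0.0946.

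Of the lists called, 8 of 14 in iWAT, 10 of 17 in eWAT, 5 of 7 in liver and 10 of 17 in BAT were called whichever library was left out, and 7, 13, 6 and 14 under all 3 scalings. Depth limits genes near the floor: Lep in liver rests on at most 1 read per library, and genes under a mean FPKM of 0.5 were not tested.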
